A study of Mus musculus with 18 samples.

How the data were processed

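Macrophages were taken from the peritoneal cavity of 5 WT and 5 HIF-1α-/- mice on C57BL/6, plated for 4 hours, washed and infected with Leishmania donovani promastigotes or left uninfected, per the labels. Strand-specific libraries were made from 100 ng of total RNA after depletion of ribosomal RNA with an RNase H method and 11 cycles of PCR, and sequenced as paired reads of 125 bases in a single lane, per the labels' protocols. The submitters' processing notes name Trimmomatic 0.36, kallisto 0.44, DESeq2 1.20.0 and R 3.5.0, without the role or order of each; the genome build and annotation release are not given in the sources used here. Genes carry Ensembl mouse identifiers, and 35471 of 35498 were matched to the GENCODE mouse annotation used here, from which gene positions were taken. Gene symbols are those deposited with the counts.

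The authors deposited 1 table of estimated counts per gene and library that are not scaled to depth, many of them not whole numbers. A second table deposited by the authors holds TPM, and every library's column in it has the same sum. The authors also deposited 4 comparison tables with DESeq2's columns: log2 fold changes with standard errors, p-values with Benjamini-Hochberg adjusted p-values, fold ratios that equal 2 to the power of the log2 value, a baseMean signal that is the mean of size-factor-scaled counts, and a Wald score that is the log2 value over its standard error. The TPM table was used for 1 alternative, the ratio of Hif1a between genotypes, because the predicted genes Gm12895 and Gm12896 took 46.5% to 67.0% of TPM but 3.30% to 7.23% of counts.

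Groups were genotype by infection, with 4 or 5 libraries each. The labels number the mice within a genotype, so an infected and an uninfected library with the same number are read as cells of the same mouse, which gives 8 complete pairs. After removal of group means, the correlation of such pairs ran from -0.084 to 0.135 and 2 of 8 lay over 0.1; the values neither require nor exclude the pairing, which rests on the labels. The main model therefore has no block, and a model with the mouse as block was an alternative (interaction 9 higher and 36 lower genes against 1 and 11 without it).

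Estimated counts were rounded and analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10, which left 11597, with TMM scaling, 1 mean per group, a robust quasi-likelihood fit and F tests of 5 contrasts: infection in each genotype, genotype in each infection state and their interaction. An adjusted p under 0.05 (Benjamini-Hochberg over all genes tested) was a call, with no fold threshold. A fold against a group with 0 counts was computed against 3 counts in each of its libraries and is a lower bound. These bounds cover counting error only. PCR reads carry no molecular identifiers and are not independent molecules. Totals of 470438 to 6338327 counts per library set the precision, and the shallowest library was WT infected 2.

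A total of 39 gene lists (24 pathways, 12 cell type markers and 3 of RNA quality or sex) were written before the data were examined, as were the contrasts, the first group of alternative settings and the rule for named genes. Each list was tested against other genes with camera on voom values with a preset correlation of 0.01 and with an estimated correlation, and alone with fry, whose PValue asks whether its genes move one way on balance. The named genes of a contrast were the 6 with the largest positive and the 6 with the largest negative log2 fold change among called genes with a mean of at least 1 CPM, a symbol that is not a predicted name, and no overlap between the groups' libraries (no overlap condition for the interaction); 20 genes fixed in advance; and up to 4 members of each list with the smallest p. Genes named outside the rule were chosen after their values were seen: Alb and other liver transcripts, Sgpp1, Pgm2, Ighm in WT cells, list members that moved against most of their list, and the olfactory receptor genes as a class. The values of 1 gene that the rule selects are not reported here.

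The first group of alternative settings held DESeq2 size factors, no filter and a stricter filter on low counts (1 CPM in 4 libraries and a mean of 50 counts), the DESeq2 1.42.0 Wald test, a fit of the compared groups alone, the mouse or replicate number as block, limma voom with the mouse as random effect, and leaving out each library in turn. Total-count scaling, thinning of all libraries to 470328 counts, and fits without WT uninfected 3 and 5 (high in liver transcripts) or without WT uninfected 1 and WT infected 2 (far out on the principal components) were added after seeing the data.

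The procedure was tested on simulated data with the same groups and depths, in which 200 genes were changed 1.5-fold, 2-fold or 4-fold. For infection in WT it called 13.4%, 53.7% and 78.8% of them, for the comparison of infected genotypes 14.9%, 41.8% and 77.3%, and for the interaction 2.99%, 23.9% and 74.2%. Of the 102, 91 and 71 genes called, 5, 2 and 4 were false. A changed list was called by camera and by fry in all 5 contrasts, and unchanged lists were called 0 times by camera and 1 time by fry. The simulated genes varied independently of each other, so these list results do not cover lists whose genes are correlated. With 200 changed genes the simulation also had far fewer changes than the real infection contrasts.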

Results

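Total RNA was sequenced from mouse peritoneal macrophages, the phagocytes that settle on the plate from cells washed out of the abdominal cavity. The labels give a design of 2 genotypes, wild type (WT) and HIF-1α-/- on C57BL/6, crossed with infection by Leishmania donovani, the protozoan agent of visceral leishmaniasis. Infected wells received promastigotes, the insect-stage form of the parasite, at 10 per cell for 6 hours. The 18 libraries comprised 5 WT uninfected, 4 WT infected, 4 knockout-labelled uninfected and 5 knockout-labelled infected. The total of the deposited estimated counts ranged from 1222673 to 2665654 per library in WT uninfected, from 470438 to 3875379 in WT infected, from 2108187 to 6338327 in knockout-labelled uninfected and from 1264624 to 2729961 in knockout-labelled infected cells. Levels are given below in CPM, counts as a share of the library total after TMM scaling, as mean ± SD over libraries. Changes are log2 fold changes with their standard errors, tested with edgeR's quasi-likelihood F test and Benjamini-Hochberg adjustment over 11597 genes. The first principal component carried 52.4% of the variance and separated all 9 infected from all 9 uninfected libraries, and the second carried 9.41%.

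The targeted gene was examined first in every library. Hif1a, the oxygen-regulated subunit of the transcription factor HIF-1, stood at 307, 373, 396, 383 and 447 CPM in WT uninfected libraries 1 to 5 and at 390, 461, 491 and 486 CPM in WT infected libraries 2 to 5. In the knockout-labelled libraries Hif1a stood at 546, 549, 707 and 673 CPM in uninfected libraries 1, 3, 4 and 5, and at 649, 695, 869, 881 and 693 CPM in infected libraries 1 to 5. The gene-level count was higher in the libraries labelled HIF-1α-/-, by 0.70 ± 0.13 on the log2 scale in uninfected cells (edgeR adjusted p = 0.00837, n = 4 and 5, a call lost in 3 alternatives) and by 0.72 ± 0.13 in infected cells (edgeR adjusted p = 0.00209, n = 5 and 4). A count summed over a whole gene cannot test the loss of part of it, and the labels do not say which part was deleted. The higher count therefore neither bears out nor contradicts the label. These libraries are called knockout-labelled throughout, and every direction drawn between genotypes below rests on the labels. Lyz2, which encodes the main lysozyme of macrophages, separated the genotypes without overlap: 18877 ± 1125 CPM in WT uninfected (n = 5) and 14660 ± 673 in WT infected cells (n = 4), against 41.0 ± 8.48 in knockout-labelled uninfected (n = 4) and 52.1 ± 14.2 in knockout-labelled infected cells (n = 5). Its neighbouring paralog Lyz1 went the other way, from 887 ± 149 CPM in WT uninfected to 3913 ± 436 in knockout-labelled uninfected cells, and reads shared between the paralogs leave the split between them uncertain.

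**Figure D1:**
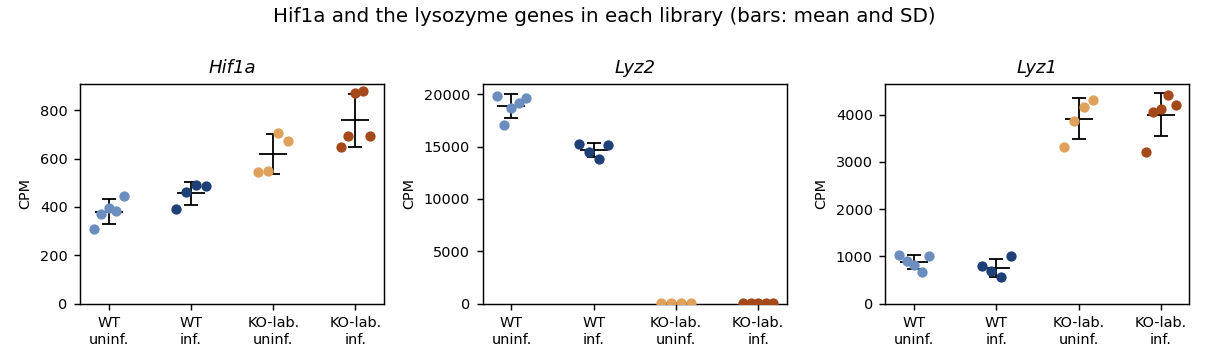
Hif1a, Lyz2 and Lyz1 in each of the 18 libraries, in CPM on the vertical axis, each gene on its own linear axis from 0, by group on the horizontal axis; points are libraries and bars mark the mean and SD. Hif1a was higher in the knockout-labelled libraries (619 ± 83.3 and 757 ± 109 CPM) than in the WT libraries (381 ± 50.2 and 457 ± 46.7 CPM), while Lyz2 was at 41.0 ± 8.48 and 52.1 ± 14.2 CPM against 18877 ± 1125 and 14660 ± 673.

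To describe the response of WT macrophages to the parasite, infected and uninfected WT libraries were compared. Genes of inflammation rose steeply. Cxcl1, a neutrophil-attracting chemokine, went from 1.49 ± 1.82 CPM (n = 5) to 540.0 ± 243 CPM (n = 4), a log2 change of 8.58 ± 0.68. The cytokine genes rose with it: Tnf by 6.31 ± 0.38, Il1b by 5.63 ± 0.54, Il6 by 3.96 ± 0.72 and the anti-inflammatory Il10 by 3.24 ± 0.63. Nos2, the inducible nitric oxide synthase, reached 11.1 ± 9.95 CPM (log2 4.88 ± 0.89), while Arg1, which competes with it for arginine, stood at 1315 ± 692 and 841 ± 117 CPM (adjusted p = 0.239). Il12b had too few counts to be tested. Among NF-kB inflammatory genes, 18 of 22 tested rose and 0 fell (19 rose when adjusted over the list alone), among them Nfkbia and Tnfaip3, which restrain the pathway, by 2.52 ± 0.14 and 3.26 ± 0.20. Of 15 chemokines tested 11 rose and 0 fell, also 11 and 0 when adjusted over the list alone, Cxcl2 by 6.95 ± 0.35 and Ccl3 by 6.13 ± 0.47. Against all other genes, camera gave adjusted p = 8.76e-11 for the NF-kB list and 3.64e-05 for the chemokines, and each had adjusted p = 0.0911 with an estimated correlation. Genes of the type I interferon response went both ways, 6 rising and 7 falling of 29 tested, the same counts when adjusted over the list alone (camera adjusted p = 0.875). Rsad2 rose by 2.42 ± 0.40 and Ddx58, a sensor of viral RNA, fell by 1.41 on the log2 scale.

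**Figure D2:**
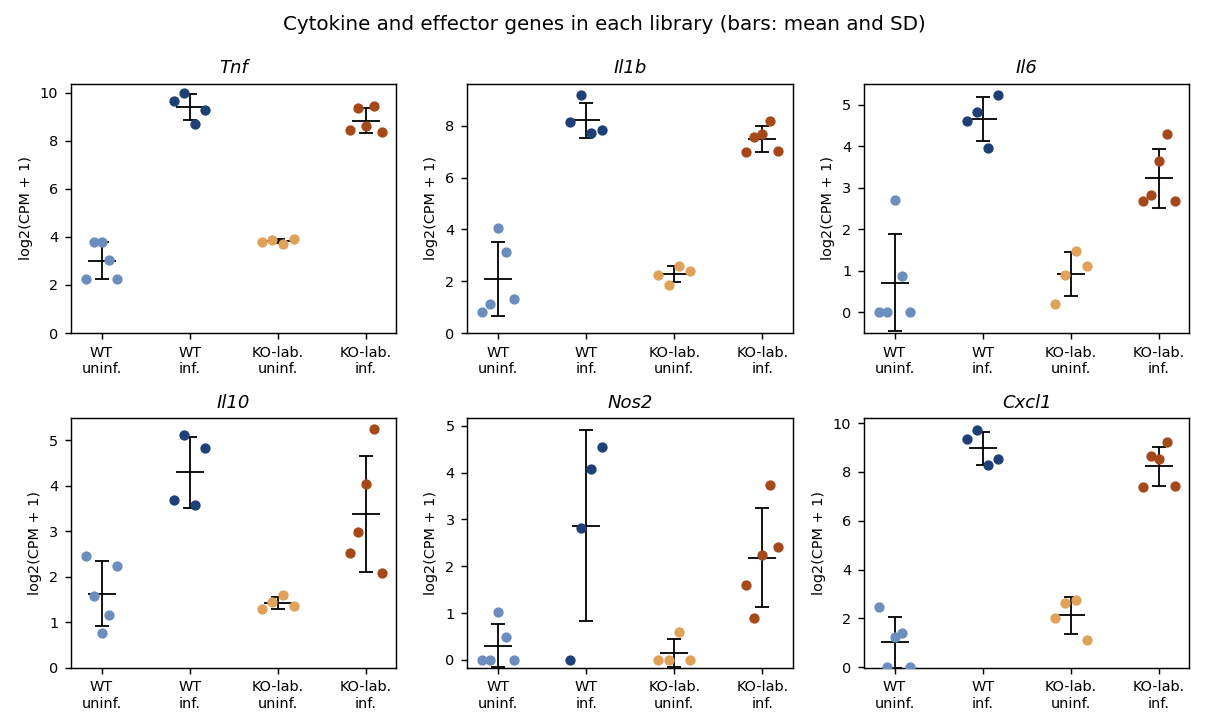
Tnf, Il1b, Il6, Il10, Nos2 and Cxcl1 in each library, as log2 of CPM plus 1 on the vertical axis and group on the horizontal axis; points are libraries and bars mark the mean and SD. The mean of each infected group lay above that of its uninfected group for all 6 genes, with Tnf at 713 ± 256 CPM in WT infected and 481 ± 177 CPM in knockout-labelled infected cells.

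Genes of glucose metabolism and of stress defence rose in the same WT comparison. Of 19 glycolysis genes tested 16 rose and 1 fell (17 and 1 when adjusted over the list alone): Pgk1 rose by 2.26 ± 0.15, Ldha, which makes lactate, by 1.65 ± 0.15, the lactate exporter gene Slc16a3 by 2.45 ± 0.15, and Pfkm fell. The glucose transporter gene Slc2a1 went from 59.7 ± 26.4 to 356 ± 27.7 CPM. Of 23 other known HIF target genes tested 16 rose and 5 fell (16 and 6 when adjusted over the list alone). Bnip3, a mitophagy receptor, rose by 1.84 ± 0.23, Ero1l by 2.61 ± 0.13, Ak4 by 6.22 ± 0.56 and the angiogenic factor Vegfa by 0.75 ± 0.13. Pdk1, which holds pyruvate back from oxidation in mitochondria, fell by 1.08 on the log2 scale together with Bnip3l, Ddit4, Cxcr4 and Selenbp1. Camera gave adjusted p = 4.45e-11 for glycolysis and 0.002 for the other HIF targets, with adjusted p = 0.115 and 0.0911 with an estimated correlation. Of 17 NRF2 and antioxidant genes 15 rose and 1 fell, also when adjusted over the list alone. Hmox1, which degrades haem, went from 705 ± 299 to 7450 ± 246 CPM, Mt1, a metal-binding metallothionein, rose by 3.73 ± 0.19 and Srxn1 by 3.46 ± 0.20 (camera adjusted p = 3.1e-10; adjusted p = 0.117 with an estimated correlation). Of 11 heat shock genes 10 rose and 0 fell, also when adjusted over the list alone, with Hsp90aa1 at 2.83 ± 0.23 (camera adjusted p = 3.58e-07; adjusted p = 0.13 with an estimated correlation). In the unfolded protein and integrated stress response list 8 of 18 rose and 0 fell (8 and 1 when adjusted over the list alone), including Atf4 by 1.77 ± 0.11 and the asparagine synthetase gene Asns by 3.36 ± 0.42 (camera adjusted p = 0.00609; adjusted p = 0.247 with an estimated correlation).

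Lists of lipid and mitochondrial genes were tested in the same WT comparison. In cholesterol biosynthesis 0 genes rose and 11 of 24 fell (12 when adjusted over the list alone), among them Fdps by 1.29 and Sc5d by 0.99 on the log2 scale (camera adjusted p = 0.0172; adjusted p = 0.621 with an estimated correlation). Of 15 SREBP-1 and fatty acid synthesis genes 3 rose and 7 fell (4 and 8 when adjusted over the list alone; camera adjusted p = 0.357). Srebf1, the regulator of that list, rose by 0.53 ± 0.13 (adjusted p = 0.00138), a call lost when libraries were scaled by their total counts. Its target Fasn stood at 75.9 ± 10.2 and 66.7 ± 16.5 CPM (adjusted p = 0.489). Scd2 fell by 1.98 and Lpin1 by 2.45 on the log2 scale. Of 14 fatty acid oxidation genes 1 rose and 6 fell, the same counts when adjusted over the list alone (camera adjusted p = 0.0759), with Cpt1a, which admits fatty acids to mitochondria, lower by a log2 change of -1.29 ± 0.21. Oxidative phosphorylation had 0 rising and 4 falling of 28 (0 and 3 when adjusted over the list alone; camera adjusted p = 0.156), led by the succinate dehydrogenase subunit Sdhb at -1.09 ± 0.18. In the mTOR pathway 4 genes rose and 5 of 18 fell (5 and 5 when adjusted over the list alone; camera adjusted p = 0.694). Mtor itself fell by 0.51 on the log2 scale (adjusted p = 0.0106), its inhibitor Deptor by 2.64 and the stress-induced Sesn1 by 3.35.

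In all, 2463 genes rose and 2601 fell with infection in WT cells by edgeR, 1162 and 1624 of them by at least 2-fold. Several of the steepest changes were from or to a group with 0 counts and are lower bounds, taken against 3 counts per library. Actc1, a cardiac actin, was at least 111-fold higher in infected cells, the long non-coding RNA U90926 at least 37.1-fold higher, Calhm5 at least 33.4-fold higher, and the olfactory receptor genes Olfr685 and Olfr1132 at least 30.3-fold and 24.5-fold higher. Hist1h2ai, Nxpe2, Rapgef4, Klhl14 and Cables1 were at least 18.1-fold, 17.4-fold, 16.2-fold, 13.8-fold and 13.2-fold lower. The split between rising and falling genes depended on the scaling. With total counts in place of TMM factors 1640 rose and 4057 fell, and the median log2 change of all genes moved from -0.09 to -0.38. With every library thinned to 470328 counts, 884 rose and 719 fell.

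To describe the response in the libraries labelled HIF-1α-/-, their infected and uninfected libraries were compared. The inflammatory genes rose here too: Tnf by 5.20 ± 0.38, Il1b by 5.53 ± 0.58, Il6 by 3.29 ± 0.77, Il10 by 2.93 ± 0.62, Cxcl1 by 6.46 ± 0.60 and Nos2 by 4.62 ± 1.02 (n = 5 and 4). Of the 22 NF-kB inflammatory genes 17 rose and 0 fell, and of the 15 chemokines 10 rose and 0 fell, in both cases also when adjusted over the list alone (camera adjusted p = 2.66e-08 and 3.51e-05; adjusted p = 0.155 and 0.0751 with an estimated correlation). The NRF2 list had 15 rising and 1 falling of 17, also when adjusted over the list alone, with Hmox1 up by 3.55 ± 0.29 and Gclc, which limits glutathione synthesis, by 2.77 ± 0.15 (camera adjusted p = 4.73e-11; adjusted p = 0.128 with an estimated correlation). All 11 heat shock genes rose, also when adjusted over the list alone (camera adjusted p = 8.8e-06; adjusted p = 0.239 with an estimated correlation). Among antimicrobial effectors 10 of 14 rose and 1 fell (11 and 1 when adjusted over the list alone), led by Acod1, which makes itaconate, at 5.17 ± 0.19, while Ncf1, a subunit of the phagocyte oxidase, fell by 0.95 on the log2 scale (camera adjusted p = 0.00343; adjusted p = 0.0544 with an estimated correlation).

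Glucose and HIF target genes went both ways in the knockout-labelled cells. Of the 19 glycolysis genes 12 rose and 2 fell (12 and 3 when adjusted over the list alone): Slc2a1 rose by 2.11 ± 0.25, Pgk1 by 1.51 ± 0.15 and Ldha by 0.80 ± 0.15, and the phosphofructokinase genes Pfkl and Pfkm fell (camera adjusted p = 0.0023; adjusted p = 0.746 with an estimated correlation). Slc16a3 stood at 29.1 ± 1.28 CPM uninfected and 22.8 ± 6.76 CPM infected. Of the 23 other HIF targets 7 rose and 9 fell (8 and 9 when adjusted over the list alone; camera adjusted p = 0.884). Pdk1 fell by 3.21 and Egln1, an oxygen-sensing prolyl hydroxylase, by 0.73 on the log2 scale, while Ak4 rose by 5.46 ± 0.71. Bnip3 went from 16.1 ± 1.51 to 9.77 ± 2.36 CPM (log2 -0.70 ± 0.27, adjusted p = 0.0374), a call that 9 alternatives did not keep. Vegfa had a log2 change of 0.21 ± 0.13 (adjusted p = 0.193). Fasn rose by 0.59 ± 0.14 and Srebf1 by 0.35 ± 0.12, the latter lost in 7 alternatives, while 7 of the 15 genes in their list fell (5 rising, and 5 and 7 when adjusted over the list alone; camera adjusted p = 0.633). In cholesterol biosynthesis 1 of 24 rose and 6 fell (1 and 4 when adjusted over the list alone; camera adjusted p = 0.0944). In all, 2523 genes rose and 2492 fell by edgeR, 1116 and 1413 of them by at least 2-fold. Actc1 was at least 112-fold, U90926 at least 52.4-fold and Otp, a homeobox gene, at least 28.6-fold higher, and Prune2, Cxxc5 and Hsf3 were at least 29.2-fold, 19.1-fold and 18.7-fold lower. With total-count scaling 1523 rose and 4200 fell, with the median log2 change of all genes at -0.36 instead of -0.04, and after thinning 857 rose and 703 fell.

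To compare the 2 responses, the log2 changes of all 11597 genes were set against each other; no library enters both. Across genes, which are not independent replicates, Pearson's r was 0.878, Spearman's rho 0.857 and the slope of the knockout-labelled on the WT response 0.815. Noise in the WT response lowers that slope, so it does not by itself show a weaker response in knockout-labelled cells. Of the genes that rose, 2006 were shared, where independent lists would share 536, and 1929 falling genes were shared where independent lists would share 559. Opposite calls were made for 6 genes. Without a filter on low counts r was 0.459.

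**Figure D3:**
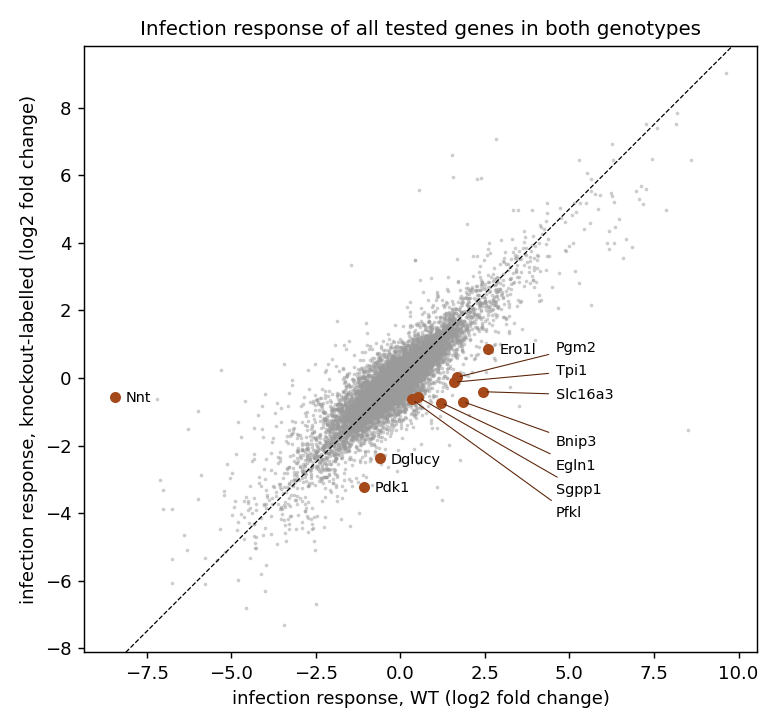
Log2 change with infection in knockout-labelled cells (vertical axis) against that in WT cells (horizontal axis), 1 point per tested gene, with 11 genes whose response differed by the interaction test named. The responses of all genes had Pearson's r 0.878 across genes, and 10 of the 11 named genes, Slc16a3 and Bnip3 among them, had a lower log2 change in the knockout-labelled than in the WT cells.

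To ask how the genotypes differed before infection, knockout-labelled and WT uninfected libraries were compared. Apart from Lyz2 (log2 -8.85 ± 0.22) and Lyz1 (2.14 ± 0.15), Axl, a receptor tyrosine kinase for apoptotic cell uptake, was higher, at 203 ± 15.3 against 83.7 ± 27.7 CPM (log2 1.31 ± 0.16, adjusted p = 6.19e-05). Psat1, an enzyme of serine synthesis, was higher by 1.36 ± 0.29, Med10 by 0.90 ± 0.17 and Wdfy1 by 0.86 ± 0.17. Lower were Clmn (log2 change -2.27 ± 0.45), Narf (-1.49 ± 0.21), the tight junction gene Tjp1 (-1.13 ± 0.21) and Dglucy (-1.11 ± 0.19). The calls of Psat1, Clmn, Wdfy1, Tjp1 and Med10 were lost in 14, 12, 8, 7 and 6 alternatives, and those of Narf and Dglucy in 1, thinning. Hist1h4m, a histone gene of a family with near-identical copies and so uncertain, was at least 116-fold lower. Of the 19 glycolysis genes 0 were higher and 2 lower (0 and 9 when adjusted over the list alone), Tpi1 with a log2 change of -0.74 ± 0.14 and Slc16a3 with -0.79 ± 0.16 (calls lost in 8 and 10 alternatives), and camera gave adjusted p = 1.3e-08 (adjusted p = 0.455 with an estimated correlation). Of the 23 other HIF targets P4ha1, a collagen prolyl hydroxylase, was lower at -0.58 ± 0.12, a call lost in 13 alternatives (0 higher and 5 lower when adjusted over the list alone; camera adjusted p = 0.000189; adjusted p = 0.0729 with an estimated correlation). Bnip3 stood at 16.1 ± 1.51 against 29.0 ± 8.76 CPM (adjusted p = 0.403). In all, 7 genes were higher and 11 lower by edgeR. The number higher was 18 without WT uninfected 1, 4 without WT uninfected 3, knockout-labelled uninfected 1 or knockout-labelled uninfected 4, and 3 without WT uninfected 4 or knockout-labelled uninfected 3. The number lower was 19 without WT uninfected 2 and 5 without WT uninfected 3, WT uninfected 4, knockout-labelled uninfected 3 or knockout-labelled uninfected 5. Transcripts of liver-secreted proteins stood out in WT uninfected 3 and 5, with Alb at 129 and 99.0 CPM of their raw totals against at most 13.5 in the other 16 libraries, and without both libraries 3 genes were higher and 7 lower.

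To ask how they differed under infection, knockout-labelled and WT infected libraries were compared. HIF target genes were lower in the libraries labelled HIF-1α-/-, whose Hif1a count was higher. Slc16a3 stood at 22.8 ± 6.76 against 278 ± 19.7 CPM (log2 -3.65 ± 0.17, edgeR adjusted p = 3.44e-15, n = 5 and 4) and Bnip3 at 9.77 ± 2.36 against 101 ± 40.7 CPM (-3.36 ± 0.26). Of 19 glycolysis genes 0 were higher and 13 lower (0 and 15 when adjusted over the list alone), with Tpi1 at -2.44 ± 0.15, Pfkl at -1.48 ± 0.14, Eno1 at -1.36 ± 0.14, Ldha at -1.29 ± 0.15 and Pgk1 at -1.15 ± 0.15, and camera gave adjusted p = 1.85e-38 (adjusted p = 0.00279 with an estimated correlation). Slc2a1 stood at 213 ± 20.4 against 356 ± 27.7 CPM (adjusted p = 0.185). Of 23 other HIF targets 0 were higher and 10 lower (0 and 18 when adjusted over the list alone), among them Ankrd37 at -5.78 ± 0.75, the prolyl hydroxylase gene Egln3 at -2.57 ± 0.40, Pdk1 at -2.41 ± 0.29 and Ero1l, which oxidises protein thiols in the endoplasmic reticulum, at -1.89 ± 0.13 (camera adjusted p = 3.41e-33; adjusted p = 1.69e-06 with an estimated correlation). Vegfa had a log2 difference of -0.34 ± 0.13 (adjusted p = 0.314).

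**Figure D4:**
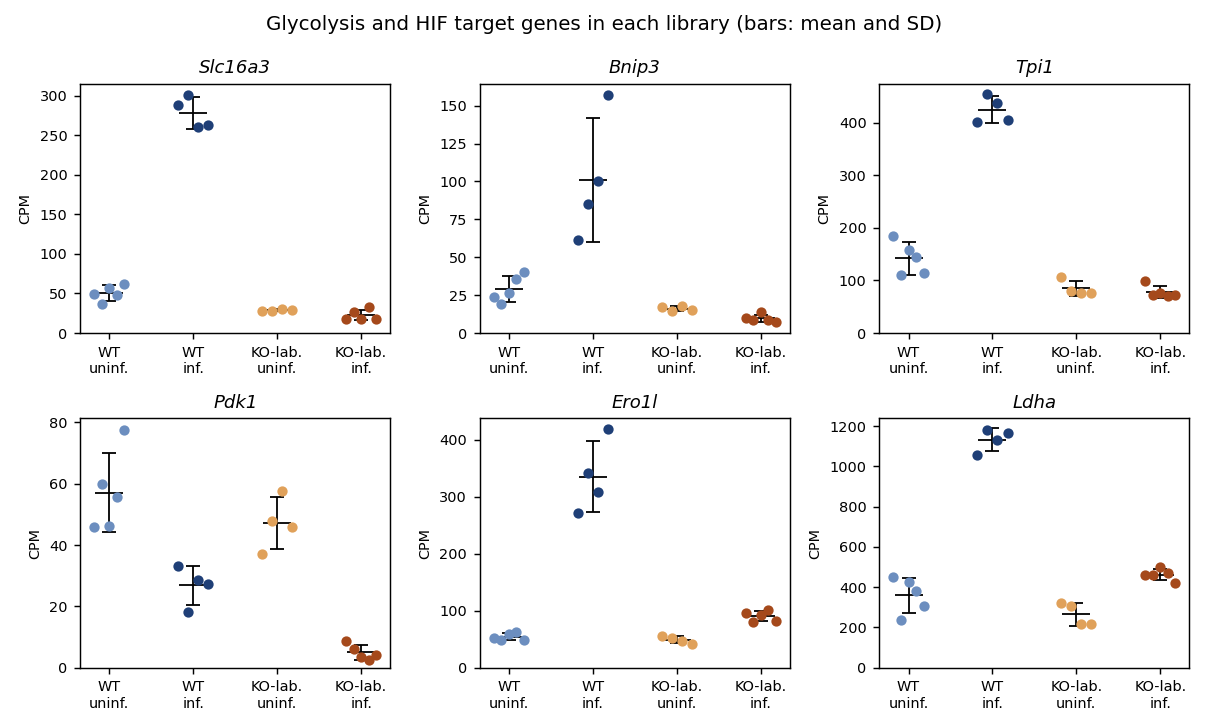
Slc16a3, Bnip3, Tpi1, Pdk1, Ero1l and Ldha in each library, in CPM on the vertical axis and by group on the horizontal axis; points are libraries and bars mark the mean and SD. In infected cells Slc16a3 was at 278 ± 19.7 CPM in WT and 22.8 ± 6.76 CPM in knockout-labelled libraries, and Ldha at 1133 ± 55.9 and 462.5 ± 27.8 CPM.

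Other genes separated the infected genotypes as well. Axl was higher by 1.47 ± 0.19, Itgal, the integrin alpha chain of LFA-1, by 1.44 ± 0.27, and Acss2, which makes acetyl-CoA from acetate, by 1.22 ± 0.28, a call lost in 5 alternatives. Fasn was higher by 0.62 ± 0.15 (edgeR adjusted p = 0.04997), a call lost in 19 alternatives. With Acss2 it made 2 of 15 SREBP-1 and fatty acid synthesis genes higher and 0 lower (3 and 0 when adjusted over the list alone; camera adjusted p = 0.201). Of 24 cholesterol biosynthesis genes 0 passed either way, also when adjusted over the list alone, with a median log2 difference of 0.23 (camera adjusted p = 0.0132; adjusted p = 0.564 with an estimated correlation). Pigf, a glycolipid anchor synthesis gene, was higher by 2.73 ± 0.67, a call lost in 17 alternatives, and the pseudogene Rps16-ps2 was higher by 1.31 ± 0.26, uncertain because it copies a ribosomal protein gene. The inflammatory genes did not pass: Tnf had a log2 difference of -0.56 ± 0.29 (adjusted p = 0.548), Il1b at -0.77 ± 0.41 (0.574), Il6 at -1.42 ± 0.62 (0.412), Nos2 at -1.44 ± 0.68 (0.47) and Arg1 at -1.02 ± 0.42 (0.391). Of 22 NF-kB inflammatory genes 0 passed, also when adjusted over the list alone, with a median log2 difference of -0.38 (camera adjusted p = 1.54e-05; adjusted p = 0.288 with an estimated correlation), and of 15 chemokines 0 passed, 4 being lower when adjusted over the list alone (camera adjusted p = 0.000546; adjusted p = 0.161 with an estimated correlation). Among immediate early genes Jun was lower, at 60.4 ± 8.59 against 121 ± 12.7 CPM (0 of 19 higher and 6 lower when adjusted over the list alone; camera adjusted p = 0.000189; adjusted p = 0.161 with an estimated correlation).

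In all, 27 genes were higher and 63 lower in infected knockout-labelled cells by edgeR. The number higher was 14 without WT infected 3 and 15 without knockout-labelled infected 5, and the number lower was 40 without knockout-labelled infected 5. DESeq2 gave 64 higher and 136 lower, the compared groups alone 45 and 112, and the fit without libraries far out on the principal components 55 and 95. After thinning, 3 were higher and 14 lower. Across genes the genotype difference in infected cells had Pearson's r 0.175 and Spearman's rho 0.0883 with that in uninfected cells; 4 higher and 8 lower genes were shared, where independent lists would share 0.0163 and 0.0598. A knockout bred from another strain can carry flanking sequence, so genes within 10 Mb of Hif1a were counted. Hif1a itself was left out of the count. Of 95 other genes tested there 0 differed between genotypes in uninfected cells (Fisher's exact test, p = 1) and 1, Sgpp1, in infected cells (p = 0.521). The numbers expected there were only 0.139 and 0.729, so the test had little power to show flanking sequence and does not exclude it.

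To ask which infection responses depended on genotype, the difference between the responses was tested as an interaction. Of 11597 genes, 11 had a lower and 1 a higher log2 change with infection in the knockout-labelled than in the WT cells by edgeR. DESeq2 gave 29 lower and 7 higher. After thinning, which leaves fewer counts and fewer genes to test, edgeR called 0 either way. There 336 genes had an unadjusted p under 0.05, some by chance alone, against 781 of 11597 without thinning. Slc16a3 differed by -2.86 ± 0.23 (adjusted p = 8.51e-09), Bnip3 by -2.54 ± 0.35 (0.000169), Pdk1 by -2.13 ± 0.35 (0.00202) and Egln1 by -1.93 ± 0.26 (0.000139). Bnip3 and Egln1 rose with infection in WT cells and fell in knockout-labelled cells. The call of the Bnip3 fall was not kept in several alternatives. Pdk1 fell in both genotypes, further in knockout-labelled cells. Of 23 other HIF targets 0 had a higher and 4 a lower log2 change, Egln1, Pdk1, Bnip3 and Ero1l (0 and 9 when adjusted over the list alone), and camera gave adjusted p = 1.06e-17 (adjusted p = 8.73e-05 with an estimated correlation). Of 19 glycolysis genes 0 had a higher and 3 a lower log2 change, Tpi1, Slc16a3 and Pfkl, the last a call lost in 12 alternatives (0 and 10 when adjusted over the list alone; camera adjusted p = 2.05e-18; adjusted p = 0.0542 with an estimated correlation). Over all comparisons, the camera calls that held with an estimated correlation were glycolysis and the other HIF targets in infected cells and the other HIF targets in the interaction. Ldha (-0.85 ± 0.21, adjusted p = 0.145), Pgk1 (-0.74 ± 0.21, 0.295), Vegfa (-0.54 ± 0.19, 0.505), Tnf (-1.11 ± 0.52, 0.737) and Fasn (0.73 ± 0.21, 0.312) did not pass.

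The 1 gene with a higher log2 change was a single gene model of Nnt, a mitochondrial transhydrogenase that carries a deletion in the C57BL/6J substrain. That model, 1 of 2 overlapping models of the gene, fell to 0 counts in WT infected cells and differed by 7.89 ± 1.22 (adjusted p = 0.00293), a fitted value that depends on the prior count. With both models summed Nnt stood at 31.1 ± 6.88, 24.2 ± 5.78, 72.2 ± 8.44 and 47.4 ± 12 CPM in WT uninfected, WT infected, knockout-labelled uninfected and knockout-labelled infected cells, and its interaction was -0.23 ± 0.29 (adjusted p = 0.959). With the mouse as a block, 9 genes had a higher and 36 a lower log2 change. The number lower was 23 without WT uninfected 1; the number higher was 5 without WT uninfected 2, 4 without knockout-labelled infected 4, 3 without WT uninfected 1, WT uninfected 4, WT infected 3 or WT infected 4, and 2 without WT uninfected 5.

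The authors' deposited comparison tables give their own calls by DESeq2 at the same threshold. They list 1981 higher and 2240 lower genes with infection in WT, 1874 and 2062 in knockout-labelled cells, 3 and 7 between uninfected genotypes and 43 and 86 between infected genotypes. Of these, 3756, 3571, 7 and 63 genes were also called here, 0 of them in the opposite direction. In the deposited tables Hif1a was higher by 0.64 ± 0.16 on the log2 scale in knockout-labelled uninfected cells (adjusted p = 0.0713, not called there) and by 0.70 ± 0.16 in infected cells (adjusted p = 0.00303). With infection in WT cells the deposited log2 changes were -0.10 ± 0.22 for Srebf1 (adjusted p = 0.781) and -0.12 ± 0.28 for Mtor (adjusted p = 0.80), neither of them called, where Srebf1 was called higher and Mtor lower here. With infection in knockout-labelled cells the deposited log2 change of Bnip3 was -0.57 ± 0.34 (DESeq2 adjusted p = 0.222), not called there, where it was called lower here. Between infected genotypes Slc16a3 stood at -3.32 ± 0.30 and Bnip3 at -3.07 ± 0.33.

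Transcripts of antigen presentation and of B lymphocytes fell together with infection. Of 10 genes of MHC class II presentation 0 rose and 9 fell in WT cells (10 when adjusted over the list alone), and 0 rose and 6 fell in knockout-labelled cells (7 when adjusted over the list alone). Ciita, the master regulator of the class, had log2 changes of -4.32 ± 0.81 and -4.67 ± 0.75 (camera adjusted p = 0.00952 and 0.0116; adjusted p = 0.621 and 0.774 with an estimated correlation). All 12 tested B cell markers fell in both genotypes, also when adjusted over the list alone, the antigen receptor subunit Cd79b with log2 changes of -3.97 ± 0.92 and -5.54 ± 1.01 (camera adjusted p = 0.0172 and 0.0045; adjusted p = 0.778 and 0.774 with an estimated correlation). Ighm, the immunoglobulin heavy chain gene with the highest level in that list, stood at 490 ± 288 and 93.8 ± 68.0 CPM in uninfected and infected WT cells and at 403 ± 98.8 and 51.8 ± 29.1 CPM in knockout-labelled cells. Summed over the lists, which share no gene, B cell transcripts stood at 1170 ± 704 CPM in the 9 uninfected and 127 ± 94.4 CPM in the 9 infected libraries, and MHC class II transcripts at 1937 ± 1008 and 645 ± 582 CPM. The other tested groups of marker genes had fewer calls. In WT cells 3 of 14 genes of large peritoneal macrophages rose, the coagulation factor gene F10 by 2.76 ± 0.23. There 3 of 10 genes of small peritoneal macrophages and monocytes fell. In CPM of raw totals the summed transcripts of that second list stood at 326 ± 82.4 uninfected and 153 ± 28.5 infected in WT cells. In knockout-labelled cells they stood at 304 ± 88.4 and 158 ± 26.5. Infected libraries had at most 191 and uninfected ones at least 238. Of 9 mast cell genes 1 fell in WT cells, Cpa3, a call lost in 18 alternatives, and 3 fell in knockout-labelled cells. In CPM of raw totals the summed mast cell transcripts stood at 388 ± 323 uninfected and 87.9 ± 87.8 infected in WT cells, and at 355 ± 82.8 and 83.8 ± 48.0 in knockout-labelled cells. Of 4 T cell genes 1 fell in WT and 2 in knockout-labelled cells. Of 5 fibroblast and endothelial genes 2 fell in WT cells, Pecam1 and Col1a2, the latter a call lost in 8 alternatives, and 1 rose and 1 fell in knockout-labelled cells. Their summed transcripts stood at 81.8 ± 30.5 and 21.4 ± 12.9 CPM of raw totals in WT cells and at 46.3 ± 13.1 and 25.2 ± 11.4 in knockout-labelled cells.

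**Figure D5:**
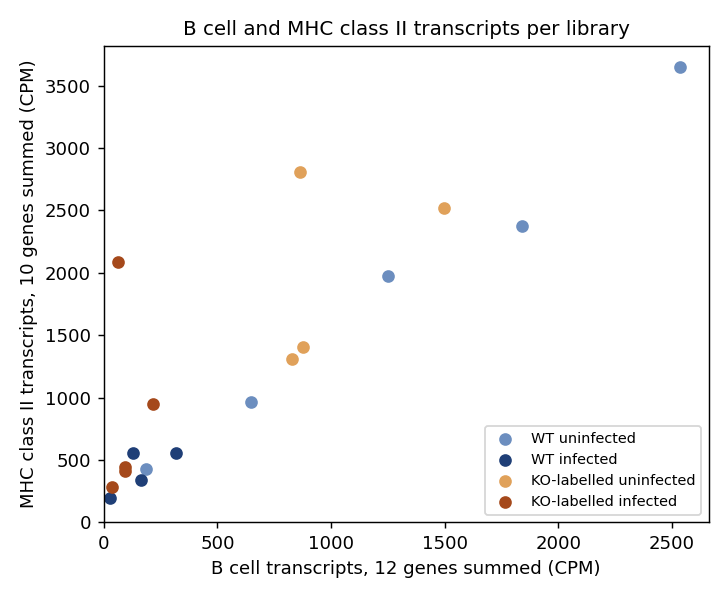
Summed CPM of 10 MHC class II genes (vertical axis) against that of 12 B cell genes (horizontal axis), 1 point per library, coloured by group. Uninfected libraries stood at 1937 ± 1008 and infected libraries at 645 ± 582 CPM of MHC class II transcripts, with knockout-labelled infected 3 at 2086 CPM.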

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

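The tests of the Lyz2 pattern and of the MHC class II pattern were chosen after the results were seen; the splits of the libraries were planned.

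Genes whose infection response differed between the genotypes by edgeR's interaction test were singled out for that difference. In log2 units, the response of the knockout-labelled cells minus that of WT cells was -2.86 for Slc16a3 (adjusted p = 8.51e-09), -1.74 for Ero1l (2.49e-06), -1.70 for Tpi1 (1.54e-05), -1.93 for Egln1 (0.000139), -2.54 for Bnip3 (0.000169) and -1.64 for Pgm2, an enzyme of sugar phosphate interconversion (0.000508). It was -2.13 for Pdk1 (0.00202), -1.11 for Sgpp1, a sphingosine phosphate phosphatase (0.00202), -1.77 for Dglucy (0.013) and -0.97 for Pfkl (0.0378). It was 7.89 for the single model of Nnt (0.00293), which the sum of both Nnt models did not keep. The list of other HIF targets differed too, with a median of -0.76 (adjusted p = 8.73e-05 with an estimated correlation). Sgpp1 lies within 10 Mb of Hif1a, where 1 of 95 tested genes other than Hif1a differed between infected genotypes.

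A gap between 1 library and the rest of its group was found in 8 of 116 groups of values examined, where chance alone gives about 1 in 20, or 5.8. WT uninfected 1 had Mtor at 103 CPM against 73.2 to 77.3 and Epas1, which encodes HIF-2α, at 212 CPM against 109 to 127. WT infected 4 had Mtor at 71.7 CPM against 47.6 to 49.6. Knockout-labelled uninfected 4 had Lyz2 at 28.4 CPM against 43.6 to 46.7, and Nos2 at 0.507 CPM against 0, a gap near the floor of counting. Summed B cell transcripts were 1497 CPM in knockout-labelled uninfected 5 against 829 to 879. Summed T cell transcripts were 16.8 CPM in knockout-labelled infected 4 against 5.80 to 8.62 over the 4 tested genes, but over all 10 listed genes it did not stand apart, at 15.5 CPM of raw totals in a group at 12.3 ± 4.30. Summed mast cell transcripts were 212 CPM in knockout-labelled uninfected 3 against 342 to 366.

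Lyz2 was nearly lost in every knockout-labelled library while Hif1a was not lower. Reads of Lyz2 counted under its paralog Lyz1 are argued against: the sum of both genes was still 5.00-fold lower in uninfected and 3.81-fold lower in infected knockout-labelled libraries, without overlap. Swapped genotype labels of infected libraries are argued against if loss of HIF-1α lowers its targets: 0 of 9 infected libraries lay on the other genotype's side by the mean log2 level of the other HIF targets, where an exchange of all labels would put all of them. An exchange of all uninfected labels is argued against if genotype differences keep their direction under infection. Genotype calls in uninfected and infected cells shared 4 higher and 8 lower genes, Lyz2, Lyz1 and Hif1a among them. Independent lists would share 0.0163 and 0.0598, and 0 calls were opposite. Nnt summed over both models, outside the pattern, was 2.34-fold higher in knockout-labelled uninfected and 1.99-fold higher in knockout-labelled infected cells. A swap of single uninfected libraries is argued against if Lyz2 marks genotype there as in infected cells. Each uninfected group would then hold both levels. Lyz2 was at most 0.247% of the WT mean in every knockout-labelled uninfected library. Lyz1 plus Lyz2 stood at 19764 ± 1168 CPM in WT and 3954 ± 434 CPM in knockout-labelled uninfected libraries, without overlap. A candidate explanation that had the values it needs is an allele placed in the Lyz2 gene, as in strains with a recombinase there, together with a partial deletion in Hif1a: Lyz2 stood at no more than 0.489% of WT, and the mean log2 levels of glycolysis and of the other HIF targets did not overlap between infected genotypes (at most 7.55 against at least 8.31, and 4.51 against 5.46). It remains a hypothesis, since the labels name no such allele and it was found and tested on the same libraries.

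MHC class II and B cell transcripts fell together with infection. Over the 9 uninfected libraries they were correlated (Pearson's r = 0.866, exact permutation p = 0.00227; Spearman's rho = 0.817, exact permutation p = 0.0108), and without the 2 libraries farthest from the median r was 0.776 (exact permutation p = 0.0347) and rho 0.786 (exact permutation p = 0.0480), the 1 relation computed in its family. Fewer B cells in the infected wells, although non-adherent cells were washed off before infection, may account for the fall, because the line through the uninfected libraries gave measured over predicted MHC class II levels with a median of 0.680 in the infected ones (bounds 0.489 to 1.25). Lower transcription in the macrophages could also do so, as the lower bound of 0.489 allows it, and the medians of 0.538 to 1.28 when any 1 uninfected library was left out keep both open: they cannot be told apart, since the ratios spread over both. Other cell types whose marker transcripts fell, such as small peritoneal macrophages and monocytes, were not tested as a source. Knockout-labelled infected 3 lay apart with a ratio of 3.70. Most infected libraries had fewer B cell transcripts than any uninfected one, of which WT uninfected 1 was lowest at 188 CPM. The line was extrapolated there, and its intercept of 487 CPM made up most of each prediction.

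Other splits of the same libraries were counted for each contrast with the same edgeR test. For infection in WT the real split called 5064 genes, 1 of 100 splits drawn from 126 called as many, the real one included, and the highest other called 3980. For infection in knockout-labelled cells these values were 5015, 1 of 100 and 3551. For the genotypes they were 18, 3 of 100 and 26 in uninfected cells, and 90, 1 of 100 and 27 in infected cells. For the interaction they were 12, 1 of 70 and 1. The share of splits calling as many genes was under 0.05 for all 5, with the mouse pairs ignored for the 2 infection contrasts. In uninfected genotypes the real split did not call the most genes. The highest other splits for infection part the libraries as the labels do but for 1 library, WT uninfected 1 or knockout-labelled infected 1. Among splits that part all 4 mouse pairs of a genotype, 11 in WT and 12 in knockout-labelled cells, the highest others called 3980 and 2577 genes against 5064 and 5015. These splits are too few for a share under 0.05, so with the pairs kept they cannot exclude chance for infection.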

How the results depend on the processing

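Total-count scaling, thinning and the fits without libraries high in liver transcripts or far out on the principal components were chosen after seeing the data. The infection counts stayed within 1.5 times of 2463 higher and 2601 lower in WT and 2523 and 2492 in knockout-labelled cells in all settings but 2. Total-count scaling gave 1640 and 4057, and 1523 and 4200, with the median log2 change of all genes at -0.38 and -0.36. Thinning to 470328 counts, which leaves fewer counts and fewer genes to test, gave 884 and 719, and 857 and 703; genotype counts of 2 and 2 uninfected and 3 and 14 infected; and interaction counts of 0 and 0 (edgeR; 336 genes at an unadjusted p under 0.05, other tools not run on thinned counts). Some of these 336 genes pass by chance alone. The genotype counts in uninfected cells were 7 and 11. They became 2 and 5 with the compared groups alone, 3 and 7 without the libraries high in liver transcripts, 17 higher without those far out on the principal components, and 18 lower with DESeq2. Leaving out 1 library gave 3 to 18 higher (18 without WT uninfected 1, 4 without WT uninfected 3 or knockout-labelled uninfected 1 or 4, 3 without WT uninfected 4 or knockout-labelled uninfected 3) and 5 to 19 lower (19 without WT uninfected 2, 5 without WT uninfected 3 or 4 or knockout-labelled uninfected 3 or 5). In infected cells the counts were 27 and 63: 41 higher with no filter, 64 and 136 with DESeq2, 45 and 112 with the compared groups alone, 55 and 95 without the libraries far out on the principal components, and 14 to 39 higher and 40 to 89 lower with 1 library left out (14 without WT infected 3, 15 and 40 without knockout-labelled infected 5). The interaction counts of 1 and 11 became 6 and 18 with no filter, 5 higher with the stricter filter, 7 and 29 with DESeq2, 9 and 36 with the mouse as block, 2 and 17 with limma voom and the mouse as random effect, 2 higher without the libraries far out on the principal components and 17 lower with total-count scaling. With 1 library left out they ran from 1 to 5 and from 10 to 23 (23 lower without WT uninfected 1; 5 higher without WT uninfected 2, 4 without knockout-labelled infected 4, 3 without WT uninfected 1 or 4 or WT infected 3 or 4, 2 without WT uninfected 5). The block moved no other count by that much, and the estimated correlation within a mouse was 0.0342. The correlation of the responses across genes was 0.459 with no filter, against 0.878. The log2 ratio of Hif1a between infected genotypes was 0.469 by the authors' TPM. Directions turned for Sdha in WT (log2 0.0148) and Acaa2 in knockout-labelled cells (0.0979) after thinning, for the B cell list between uninfected genotypes (camera adjusted p = 0.0326) and the mast cell list in the interaction (0.0303) with the replicate block, and for the median of the NRF2 list in the interaction without WT uninfected 1 (-0.0215; over single libraries left out, from -0.0215 to 0.358). Of 333 calls of named genes 126 were lost or turned in at least 1 setting, for most of them with thinning. Except where the construction shows it, the cause was not tested.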

Other observations

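The tests of the olfactory receptor pattern were planned before their results were seen, except that of reads shared between risen members; the choice of that gene class, and of the liver and Nnt values, came after the data were examined.

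Genes of microbial sensing and of iron handling changed in infected cells of both genotypes, with members going both ways. Of 19 pattern recognition receptor genes 10 rose and 4 fell in WT cells, also when adjusted over the list alone, and 12 rose and 2 fell in knockout-labelled cells (13 and 3 when adjusted over the list alone). Clec4e, a receptor for microbial glycolipids, rose by 4.75 ± 0.19 and 4.74 ± 0.21 on the log2 scale, and the inflammasome gene Nlrp3 by 2.96 ± 0.15 and 2.03 ± 0.15 (camera adjusted p = 0.000981 and 0.000209; adjusted p = 0.0911 and 0.0544 with an estimated correlation). Of 12 iron handling genes 8 rose and 2 fell in each genotype, also when adjusted over the list alone, with the importer gene Slc11a2 at 2.83 ± 0.12 and 2.55 ± 0.12 and the exporter gene Slc40a1, ferroportin, at 2.07 ± 0.25 and 2.56 ± 0.22 (camera adjusted p = 0.00335 and 0.00251; adjusted p = 0.282 and 0.36 with an estimated correlation). In the autophagy and mitophagy list 5 genes rose and 7 of 18 fell in WT cells, also when adjusted over the list alone (camera adjusted p = 0.987). Its cargo receptor gene Sqstm1, which is also an NRF2 target, rose by 2.86 ± 0.14.

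Of 128 tested olfactory receptor genes, first known from smell, 14 rose and 8 fell with infection in WT cells, and 11 of the 14 rose in knockout-labelled cells as well. Both shares were smaller than those over all 11597 tested genes, of which 2463 rose and 2601 fell in WT cells. The counts therefore do not show a response of the class, and the tests below concern the 14 risen members only. Transcription running on from a risen gene upstream is argued against: 0 of the 14 had such a gene ending within 50 kb on the same strand (upper 95% bound 23.2%; 1 of 114 other members; Fisher's exact test, p = 1). Reads shared between risen members are argued against by their sequences, since 0 of the 14 shared 20% or more of their 31-base words with another risen member, the highest share being 0.583%. Reads of another risen gene with near-identical sequence are argued against too, since 0 of the 14 shared that much with a gene that rose, the highest share being 1.98%. Against any other gene the shares had a median of 9.09% and reached 29.2%, and what the counts stand for stays open.

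Transcripts of liver-secreted proteins were high in WT uninfected 3 and 5. In CPM of raw totals, Apob stood at 28.1 and 27.0 against at most 6.38 in the other 16 libraries, Fga at 13.1 and 7.36 against at most 0.758, and Ttr at 7.50 and 13.1 against at most 0.919. Nnt summed over both models was 2.34-fold higher in knockout-labelled than in WT uninfected cells (edgeR adjusted p = 0.000588) and 1.99-fold higher in infected cells (edgeR adjusted p = 0.0204). Whether the genotypes also differ in substrain was not tested, and such a difference would enter every genotype contrast.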
